A study of Mus musculus with 15 samples.

How the data were processed

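Liver RNA from 15 mouse samples was made into libraries with the Illumina TruSeq mRNA kit and sequenced, per the labels' protocols. The deposited values are raw read counts per gene symbol, 1 table per library, which the authors made with the aligner GSNAP against the mouse build mm10, per the submitters' processing notes. Those notes also name DESeq2 1.12.3. The counting program, the gene annotation and the use of strand are not given in the sources used here. Each table also held 5 entries for reads given to no gene, which were left out of library sizes and tests. Gene counts ran from 10347844 to 28843258 per library and were 41.4% to 53% of the reads listed. Between 16159 and 17530 genes were detected per library. Replicate libraries differed by more than counting error, by a chi-square per degree of freedom over genes with a summed count of at least 20. It was 3.93 for the CCl4 day 0 pair, the closest, and 19.4 to 78.4 for the other pairs.

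Libraries were grouped by treatment, feeding and day as the labels give them, in 8 groups. The names of the deposited tables give 28D where the labels give day 20 or day 23, and the labels were followed. Symbols of 23680 genes matched GENCODE M21, from which coordinates on mm10 were taken. Reads that aligned to more than 1 place, 18.1% to 28.8% of the reads listed, had an entry of their own and were not counted for genes. Values of genes with close copies, such as Cyp2b, Cyp2c, Cyp2a, Cyp4a12, Saa and Orm genes, are therefore uncertain.

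The 8 tested comparisons, their tests, 31 gene lists and the rule for named genes were fixed before the data were examined. Counts were scaled by TMM, filtered with filterByExpr to 14778 genes, and fitted with edgeR 4.0.16 in R 4.3.3 with 1 mean per group, which left 7 residual degrees of freedom. The common dispersion was 0.0414 and the prior degrees of freedom were 4.43. Each comparison was tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 are called. A group with 1 library has no spread of its own, so it is assumed to vary like the other groups. CPM values are TMM-normalised, except the pancreas levels of single libraries, and SD is the spread between libraries of a group. On the log2 scale a prior count of 2 was added for ratios of single libraries.

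For lists, 31 sets of genes written from general knowledge were tested with limma 3.58.1. Camera was run with a preset inter-gene correlation of 0.01 and with an estimated correlation. Fry tests whether a set's genes move on balance in a single direction and does not compare the set with other genes. Adjustment was over the lists of a comparison, and members were also adjusted over the list alone. Lists needed at least 3 tested members. With the preset correlation 147 list tests passed, of which 13 passed with an estimated correlation. At day 23 a list's median was set against 10000 random lists matched on mean expression within 100 ranks.

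Named genes are, per comparison, up to 6 called genes per direction with the largest log2 change, a group mean of at least 5 CPM and no overlap between the groups' libraries, leaving out unnamed transcripts, immunoglobulin and T cell receptor segments and Mup genes. Up to 4 members with the smallest adjusted p were taken from lists with at least 3 called members, and 19 genes were fixed whatever their p. Of these 19, the number that passed was 4 for CCl4 at day 0, 2 for ethanol in OO animals, 1 for ethanol in CCl4 animals, 9 for CCl4 under ethanol, 0 for CCl4 under chow, 3 for CCl4 with ethanol against OO chow, 0 for the interaction and 11 for day 20 against day 0.

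The test was tested on simulated data for the 14778 genes, with 200 genes changed 2-fold or 4-fold. In the design of CCl4 under ethanol it called 62% of genes changed 2-fold and 93% of those changed 4-fold, and 7.74% of its calls were false. In that of CCl4 under chow the shares were 14% and 65%, with 5.95% false, and in that of the interaction 7% and 68%, with 3.85% false. Of 100 unchanged lists in each design 0 were called by camera. The simulated genes were drawn independently of each other, so this does not test false calls for lists of correlated genes. Apart from the changed genes, all libraries were drawn around a common mean per gene. The shares therefore do not cover a single control library that stands apart. Genes with a low mean were not picked for change.

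Alternatives were RLE scaling, no filter, a filter of 1 CPM in 2 libraries, a tested fold of 1.5 with glmTreat, DESeq2 1.42.0, limma-voom with and without lane as a random block, fits on fewer libraries, day 20 and day 23 libraries merged, and each library left out. Added after the data were seen were the day 23 chow library in place of the day 20 chow library, the fit without libraries 6 and 12, the agreement of the CCl4 effects under ethanol and chow, list tests of the interaction and of ethanol in OO animals with the day 23 chow library, and 3 lists of sex-biased liver genes. The day 23 pair has 1 library per group and was not tested. Pairing was not used, since groups share no replicate numbers.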

Results

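Messenger RNA was sequenced from whole livers of adult male C57BL/6 mice in 15 libraries, 1 per sample in the labels. The arms differed in carbon tetrachloride (CCl4), a solvent that liver cytochrome P450 turns into a toxic radical, and in ethanol given into the stomach by tube. The labels name the arm without CCl4 OO and do not spell the name out, so it is kept here. CCl4 animals received 0.2 ml/kg 2 times a week for 6 weeks, and those taken at day 20 then received it at 0.5 of that dose. Ethanol reached 25 g/kg per day over 3 weeks. In the labels the ethanol arms carry a high-fat diet and the control arms chow, so every ethanol comparison is also a comparison of diets. The groups were OO at day 0 (n = 2), CCl4 at day 0 (n = 2), OO with chow at day 20 (n = 1), OO with ethanol at day 20 (n = 3), CCl4 with chow at day 20 (n = 2) and CCl4 with ethanol at day 20 (n = 3). At day 23 there was 1 OO library with chow and 1 with ethanol. The labels place the day 23 libraries in a different substudy from the day 20 libraries. They also name OO again for the second phase of the day 20 OO arms (OO+OO/chow, OO+OO/EtOH). For the day 23 arms (OO+chow, OO+EtOH) they do not, so the second phase may differ in that as well. Libraries are named by the number in their labels, which do not say that each came from a separate animal, so p-values measure the spread between these samples.

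Counts assigned to genes were 11448618 and 13115579 in the OO day 0 libraries 1 and 2, and 16630912 and 10347844 in the CCl4 day 0 libraries 3 and 4. They were 14999801 in the day 23 chow library 5, 28843258 in the day 23 ethanol library 6 and 12376433 in the day 20 OO chow library 12. The day 20 OO ethanol libraries 13, 14 and 15 held 10973803, 19332746 and 11876098. The day 20 CCl4 chow libraries 16 and 17 held 12682848 and 13430034, and the day 20 CCl4 ethanol libraries 18, 19 and 20 held 21880629, 16246015 and 11189327. The filter on low counts left 14778 genes. The first principal component held 36.9% of the variance and the second 17.1%.

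Transcripts of the exocrine pancreas, the tissue that secretes digestive enzymes, stood out in 2 libraries of different arms. Summed over the pancreas genes, the level without TMM scaling was 178 CPM, counts relative to library size, in the day 20 OO chow library 12 and 162 CPM in the day 23 OO ethanol library 6, against a median of 8.87 CPM over all libraries. Library 12 is the single control of 3 comparisons below and enters the interaction, so the number of calls in each of those is also given with the day 23 OO chow library 5 in its place. That exchange was chosen after the data were seen. Library 5 also differs from library 12 in day, in substudy and in the second-phase OO of the labels.

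The day 0 comparison asks what 6 weeks of CCl4 had done to the liver before any ethanol. Genes called lower in CCl4 livers included acute-phase genes, which encode plasma proteins that hepatocytes secrete in inflammation. Lcn2, encoding the iron-siderophore binding protein lipocalin 2, stood at 6.56 ± 2.85 CPM after CCl4 and 726 ± 634 CPM in OO livers (SD, n = 2 in each), a log2 change of -6.76 ± 0.81 (SE; adjusted p = 0.00158 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Orm2, an acid glycoprotein, fell 60.2-fold, and haptoglobin (Hp), which binds free haemoglobin, fell 4.64-fold from 10640 ± 3126 to 2290 ± 135 CPM (SD, n = 2). The serum amyloid A gene Saa1 fell by 6.12 on the log2 scale, a call lost without library 3 (edgeR adjusted p = 0.0542) or library 4 (0.0554); its close copy Saa2 makes the value uncertain. The spread between the OO libraries was wide, with an SD of 1993 CPM around the Saa1 mean of 3388 CPM. Lcn2 lies on chromosome 2 at 32384633 to 32388252 on the minus strand of mm10, and Saa1 on chromosome 7 at 46740497 to 46742980 on the minus strand.

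Of the 22 acute-phase genes tested at day 0, 13 fell, and 21 fell when adjusted over the list alone (limma's fry, adjusted p = 0.00771; camera, adjusted p = 0.0979 with an estimated correlation). In the matrix list 7 of 28 rose, and 18 rose when adjusted over the list alone (fry, adjusted p = 0.0387; camera, adjusted p = 0.28 with an estimated correlation). Among them were the collagenase Mmp2, higher by 2.42 ± 0.36 on the log2 scale, and the matricellular protein gene Postn, higher by 1.66 ± 0.24 (SE); without library 3 these calls were lost (edgeR adjusted p = 0.0596 and 0.058), and Postn's also without library 2 (0.0506). In the Kupffer cell and macrophage list 3 of 14 fell, and 10 fell when adjusted over the list alone (fry, adjusted p = 0.00771; camera, adjusted p = 0.105 with an estimated correlation). Cd163, the macrophage receptor for haptoglobin-haemoglobin complexes, fell 4.72-fold to 12 ± 1.16 CPM (SD, n = 2). Gpnmb, a glycoprotein of lipid-loaded macrophages, rose from 0.315 ± 0.333 to 26.4 ± 3.6 CPM (SD, n = 2), a call lost without library 2 (edgeR adjusted p = 0.0507).

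In the periportal list of the day 0 comparison 4 of 16 rose, 5 rose and 1 fell when adjusted over the list alone (fry, adjusted p = 0.00771; camera, adjusted p = 0.0979 with an estimated correlation), among them the glutaminase gene Gls2 at 719 ± 16.8 against 327 ± 21.1 CPM (SD, n = 2). In the pericentral list 4 of 16 fell, the same number when adjusted over the list alone, although fry gave an adjusted p of 0.1 and camera an adjusted p of 0.404 with an estimated correlation. One of them, the glutamine synthetase gene Glul, fell from 951 ± 91.9 to 181 ± 3.22 CPM (SD, n = 2), a call lost without library 3 (edgeR adjusted p = 0.0553) or library 4 (0.0532). No cell cycle gene passed over all genes, and 9 of 28 were higher when adjusted over the list alone (fry, adjusted p = 0.149; camera, adjusted p = 0.404 with an estimated correlation). Across all genes edgeR called 304, of which 140 were higher and 164 lower after CCl4. Leaving out library 1, 2, 3 or 4 gave 121, 120, 54 or 52 genes. A fit on only the 4 compared libraries gave 2240, and DESeq2 gave 734, 388 higher and 346 lower.

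**Figure D1:**
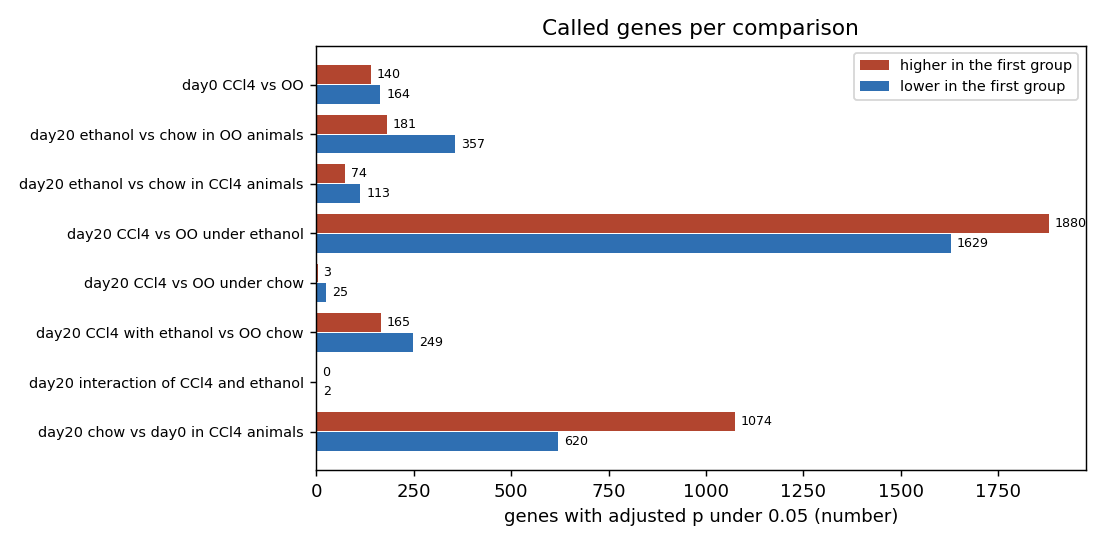
Number of genes called by edgeR at an adjusted p under 0.05 in each comparison, as horizontal bars for genes higher (red) and lower (blue) in the first group. CCl4 against OO gave 1880 higher and 1629 lower genes under ethanol, and 3 and 25 under chow.

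Ethanol against chow in OO animals at day 20 asks what ethanol feeding did without CCl4. Genes called higher included cytochrome P450 genes of families that handle drugs and foreign compounds. Cyp2b10, a standard target of the nuclear receptor CAR, stood at 1093 ± 318 CPM with ethanol (SD, n = 3) and 4.27 CPM in the chow library, 256-fold higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000637). Cyp2b9 rose 163-fold to 169 ± 57.1 CPM, Cyp2c55 rose 18.4-fold, and the abundant Cyp2c29 rose 8.82-fold to 8978 ± 694 CPM (SD, n = 3). These families hold close copies, and reads that aligned to more than 1 place were not counted, so the values of single members are uncertain. Cyp2b10 lies on chromosome 7 at 25897620 to 25926624 on the plus strand of mm10.

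In the P450 list 11 of 27 rose with ethanol, and 18 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0119 with an estimated correlation). In the glutathione and NRF2 list, genes that conjugate and reduce reactive compounds, 10 of 21 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0119 with an estimated correlation). Cbr3, a carbonyl reductase, rose 30.2-fold to 26.4 ± 8.57 CPM, and Ephx1, the microsomal epoxide hydrolase, rose 3.19-fold to 896 ± 22.2 CPM (SD, n = 3). Among transporters, the efflux pump gene Abcc4 rose 11.2-fold to 107 ± 19.3 CPM, while the organic anion uptake gene Slco1a1 fell 10.1-fold to 26.5 ± 17.6 CPM (SD, n = 3). In the list of fatty acid oxidation and PPARA targets 6 of 26 rose, and 14 rose when adjusted over the list alone (fry, adjusted p = 0.0265; camera, adjusted p = 0.163 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase and PPARA target, rose from 6.01 to 192 ± 92.2 CPM (SD, n = 3), a call lost without library 14 (edgeR adjusted p = 0.0569). With the day 23 chow library as control, Cyp2b10 kept a log2 change of 7.85 (edgeR adjusted p = 0.000401), Cbr3 5.22 (0.00114) and Abcc4 3.73 (0.000401), while Cyp4a14 at 4.19 had an adjusted p of 0.124, and 0.063 on only the 9 day 20 libraries. As lists against that library, a test chosen after the data were seen, the P450 and the glutathione and NRF2 genes passed at medians of 1.08 and 2.32 (camera, adjusted p = 0.0117 and 0.00892 with an estimated correlation). The PPARA targets did not, at a median of 0.56 (fry, adjusted p = 0.14; camera, adjusted p = 0.408 with an estimated correlation).

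Genes called lower with ethanol than in the day 20 chow library included interferon-stimulated, macrophage and lymphocyte genes. In the interferon-stimulated list 11 of 20 fell, and 15 fell when adjusted over the list alone (camera, adjusted p = 0.0384 with an estimated correlation). In the Kupffer cell list 7 of 14 fell, and 13 fell when adjusted over the list alone (camera, adjusted p = 0.0367 with an estimated correlation). The monocyte list had 7 of 16 lower and the neutrophil list 3 of 15, and 10 and 9 fell when adjusted over the list alone (camera, adjusted p = 0.0993 with an estimated correlation for both). In the lymphocyte list 3 of 17 fell, and 4 fell when adjusted over the list alone (fry, adjusted p = 0.00796; camera, adjusted p = 0.0993 with an estimated correlation); against the day 23 chow library its median was -0.79 (fry, adjusted p = 0.0759; camera, adjusted p = 0.229 with an estimated correlation). Set against the day 23 chow library, the macrophage growth factor receptor gene Csf1r went from a log2 change of -1.29 (edgeR adjusted p = 0.0019) to -0.47 (adjusted p = 0.24). The antiviral gene Rsad2 went from -1.50 (0.0054) to -0.11 (0.901), and the lysozyme gene Lyz2 from -2.08 (0.00728) to -0.83 (0.328). Cd74, of antigen presentation, stood at -1.72 (0.0229) and at -1.75 (0.0513), and its call was also lost without library 14 (0.0557) and on only the 9 day 20 libraries (0.0793). As lists against the day 23 chow library, 19 of 20 interferon-stimulated genes had a negative log2 change with a median of -0.55, and 13 of 14 Kupffer cell genes with a median of -0.34. Neither list passed there (fry, adjusted p = 0.0759 and 0.114; camera, adjusted p = 0.229 and 0.332 with an estimated correlation). The monocyte list had a median of 0.062 there, with 9 of 16 members positive, and the neutrophil list 0.030, with 8 of 15 positive (fry, adjusted p = 0.996 for both). In the matrix list 5 of 28 fell, and 17 fell when adjusted over the list alone (fry, adjusted p = 0.0265; camera, adjusted p = 0.163 with an estimated correlation); its elastin gene Eln went from -2.04 (edgeR adjusted p = 0.0099) to -0.20 (0.889). Against the day 23 chow library the matrix list had a median of 0.10, with 16 of 28 positive (fry, adjusted p = 0.996). The cell cycle inhibitor gene Cdkn1a went from -3.37 (0.0118) to -0.49 (0.844).

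Exocrine pancreas genes were lower than in library 12, 10 of 12 over all genes and 12 when adjusted over the list alone (camera, adjusted p = 0.00864 with an estimated correlation); the elastase gene Cela2a stood at 25.4 CPM in the chow library and 0.106 ± 0.141 CPM with ethanol (SD, n = 3). Against the day 23 chow library 9 of the 12 had a positive and 1 a negative log2 change, and the list did not pass with fry or camera. Outside library 12 and the day 23 ethanol library, these genes reached at most 1.74 CPM without TMM scaling, apart from Cela1. Those signs therefore come from low levels. Across all genes edgeR called 538 in this comparison, 181 higher and 357 lower with ethanol. With the day 23 chow library as control there were 93 calls, 56 higher and 37 lower, of which 70 were among the 538. DESeq2 also called more genes higher (514) than lower (439), so the balance of directions depends on the setting. Leaving out library 13 gave 1554 genes, 849 higher and 705 lower, and leaving out library 15 gave 253, and the single chow library is assumed to vary like the other groups.

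Ethanol against chow in CCl4 animals at day 20 asks what ethanol added to the CCl4 injury. P450 genes were again among those that rose: Cyp2c29 from 299 ± 28.7 CPM (SD, n = 2) to 5557 ± 988 CPM (SD, n = 3), 18.6-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.11e-05), Cyp2b10 56.9-fold and Cyp2b9 263-fold (adjusted p = 0.000102 for both). Hsd3b5, a steroid dehydrogenase that male mouse livers express more than female livers, fell from 29.5 ± 16 CPM (SD, n = 2) to 0.153 ± 0.0265 CPM (SD, n = 3), and the male-biased fatty acid hydroxylase gene Cyp4a12a fell 67.4-fold (edgeR adjusted p = 0.00152). In bile acid and transport genes, the oxysterol hydroxylase gene Cyp7b1 fell 9.19-fold to 14.3 ± 4.2 CPM and Slco1a1 fell 29.6-fold to 6.17 ± 0.977 CPM (SD, n = 3). Hsd3b5 lies on chromosome 3 at 98618634 to 98630252 on the minus strand of mm10.

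In the P450 list of the CCl4 animals 10 of 27 rose and 1 fell with ethanol, and 14 rose and 3 fell when adjusted over the list alone (fry, adjusted p = 0.00288; camera, adjusted p = 0.0735 with an estimated correlation). The bile acid list had 3 of 20 lower, and 1 higher and 5 lower when adjusted over the list alone (fry, adjusted p = 0.0434; camera, adjusted p = 0.386 with an estimated correlation). In the interferon-stimulated list 1 of 20 fell, and 16 fell when adjusted over the list alone (fry, adjusted p = 0.0176; camera, adjusted p = 0.117 with an estimated correlation). Genes of fat cells gave 1 call of 5, lower, and 4 fell when adjusted over the list alone (fry, adjusted p = 0.00785; camera, adjusted p = 0.0777 with an estimated correlation). The glutathione and NRF2 list, with 10 higher members in OO animals, had 1 of 21 higher here, the same count when adjusted over the list alone, and a median log2 change of -0.15. No gene of the matrix list passed over all genes, with 1 of 28 higher and 2 lower when adjusted over the list alone (fry, adjusted p = 0.504; camera, adjusted p = 0.613 with an estimated correlation). Across all genes edgeR called 187, 74 higher and 113 lower with ethanol, against 412 by DESeq2 and 99 in a fit on only the compared libraries. Leaving out library 16, 17 or 20 gave 49, 54 or 72 genes.

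CCl4 against OO under ethanol at day 20 asks how the double injury differed from ethanol alone, with 3 libraries in each group. Genes called higher included macrophage, matrix and cell division genes, and genes called lower included P450 genes. Gpnmb rose 63.5-fold from 4.67 ± 2.41 to 304 ± 118 CPM (SD, n = 3; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.02e-05). Trem2, a lipid receptor of macrophages, rose 16-fold to 28.5 ± 4.95 CPM, and Spp1, encoding the matrix protein osteopontin, rose 9.06-fold to 503 ± 114 CPM (SD, n = 3). The proliferation marker gene Mki67 rose 23.7-fold from 5.93 ± 1.39 to 142 ± 75.8 CPM, and Col3a1, a fibrillar collagen, rose 5.76-fold to 495 ± 191 CPM (SD, n = 3). On the lower side, Cyp2e1, the P450 that oxidises ethanol and activates CCl4, fell 9.1-fold from 4098 ± 1555 to 450 ± 269 CPM, and the coumarin hydroxylase gene Cyp2a5 fell 99.3-fold to 31.8 ± 18.6 CPM (SD, n = 3). Gpnmb lies on chromosome 6 at 49036546 to 49070929 on the plus strand of mm10, and Cyp2e1 on chromosome 7 at 140763739 to 140774987 on the plus strand.

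The matrix list had 26 of 28 genes higher, the same number when adjusted over the list alone (fry, adjusted p = 0.000471; camera, adjusted p = 0.104 with an estimated correlation). In the stellate cell and myofibroblast list 8 of 18 rose and 1 fell, over all genes and when adjusted over the list alone (fry, adjusted p = 0.00376, and camera, adjusted p = 0.206 with an estimated correlation). Among the higher genes was the growth factor receptor gene Pdgfra, 3.64-fold higher at 66.8 ± 17.3 CPM (SD, n = 3). Acta2, of the same list, was not called, with log2 changes of -0.42 to 0.39 when 1 library was left out. The monocyte and lipid-associated macrophage list had 15 of 16 higher and 16 when adjusted over the list alone (fry, adjusted p = 0.000234; camera, adjusted p = 0.0994 with an estimated correlation). In the Kupffer cell list 9 of 14 rose and 1 fell, with 10 and 2 when adjusted over the list alone (fry, adjusted p = 0.000725; camera, adjusted p = 0.127 with an estimated correlation). The neutrophil list had 11 of 15 higher and 12 when adjusted over the list alone (fry, adjusted p = 0.00139; camera, adjusted p = 0.117 with an estimated correlation), with the lactoferrin gene Ltf 29.3-fold higher. In the cell cycle list 24 of 28 rose, and 28 rose when adjusted over the list alone (fry, adjusted p = 0.00247; camera, adjusted p = 0.134 with an estimated correlation). Bile duct and ductular genes had 7 of 13 higher and 8 when adjusted over the list alone (fry, adjusted p = 0.00124, and camera, adjusted p = 0.117 with an estimated correlation). Krt19, of the same list, was not called, with log2 changes of -0.33 to 0.13 when 1 library was left out. In the p53 list 7 of 16 rose, with 8 higher and 1 lower when adjusted over the list alone (fry, adjusted p = 0.00136; camera, adjusted p = 0.117 with an estimated correlation), including Cdkn1a, 5.45-fold higher at 8.15 ± 1.99 CPM (SD, n = 3).

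In the CCl4 animals under ethanol the P450 list had 18 of 27 lower and 1 higher, with 18 lower and 2 higher when adjusted over the list alone (fry, adjusted p = 0.000234; camera, adjusted p = 0.0994 with an estimated correlation). In the bile acid list 12 of 20 fell and 15 when adjusted over the list alone (fry, adjusted p = 0.000251; camera, adjusted p = 0.0994 with an estimated correlation), with Cyp7b1 12.2-fold lower at 14.3 ± 4.2 CPM (SD, n = 3). Cholesterol synthesis had 17 of 22 lower and 19 when adjusted over the list alone (fry, adjusted p = 0.0081; camera, adjusted p = 0.197 with an estimated correlation). In the glutathione and NRF2 list 12 of 21 fell and 2 rose, with 14 and 2 when adjusted over the list alone (fry, adjusted p = 0.000251, and camera, adjusted p = 0.0994 with an estimated correlation). Cbr3 was 8.82-fold lower at 3 ± 0.0392 CPM (SD, n = 3). The same OO ethanol libraries gave the rise of the P450 and the glutathione and NRF2 lists with ethanol in OO animals. The falls here are therefore not independent of that rise, and the interaction below uses these libraries too. Genes of ethanol and acetaldehyde metabolism had 9 of 13 lower and 1 higher, with 11 and 2 when adjusted over the list alone (fry, adjusted p = 0.000471; camera, adjusted p = 0.104 with an estimated correlation). In the pericentral list 7 of 16 fell and 1 rose, with 8 and 1 when adjusted over the list alone (fry, adjusted p = 0.00376; camera, adjusted p = 0.227 with an estimated correlation), with Glul 4.4-fold lower at 152 ± 55.1 CPM (SD, n = 3). In the hepatocyte identity list 5 of 22 fell and 1 rose, with 6 and 2 when adjusted over the list alone (fry, adjusted p = 0.0177; camera, adjusted p = 0.294 with an estimated correlation), with Cebpa 1.68-fold lower at 124 ± 11.5 CPM and Trf 1.95-fold higher at 38810 ± 4345 CPM (SD, n = 3). The fatty acid synthesis list had 2 of 18 lower and 2 higher, the same numbers when adjusted over the list alone (fry, adjusted p = 0.405; camera, adjusted p = 0.75 with an estimated correlation). Across all genes edgeR called 3509, with 1880 higher and 1629 lower in CCl4 livers. Leaving out library 18 gave 2223 genes, the lowest count over the 6 libraries, and a fit on only the compared libraries gave 2319, 1513 higher and 806 lower.

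**Figure D2:**
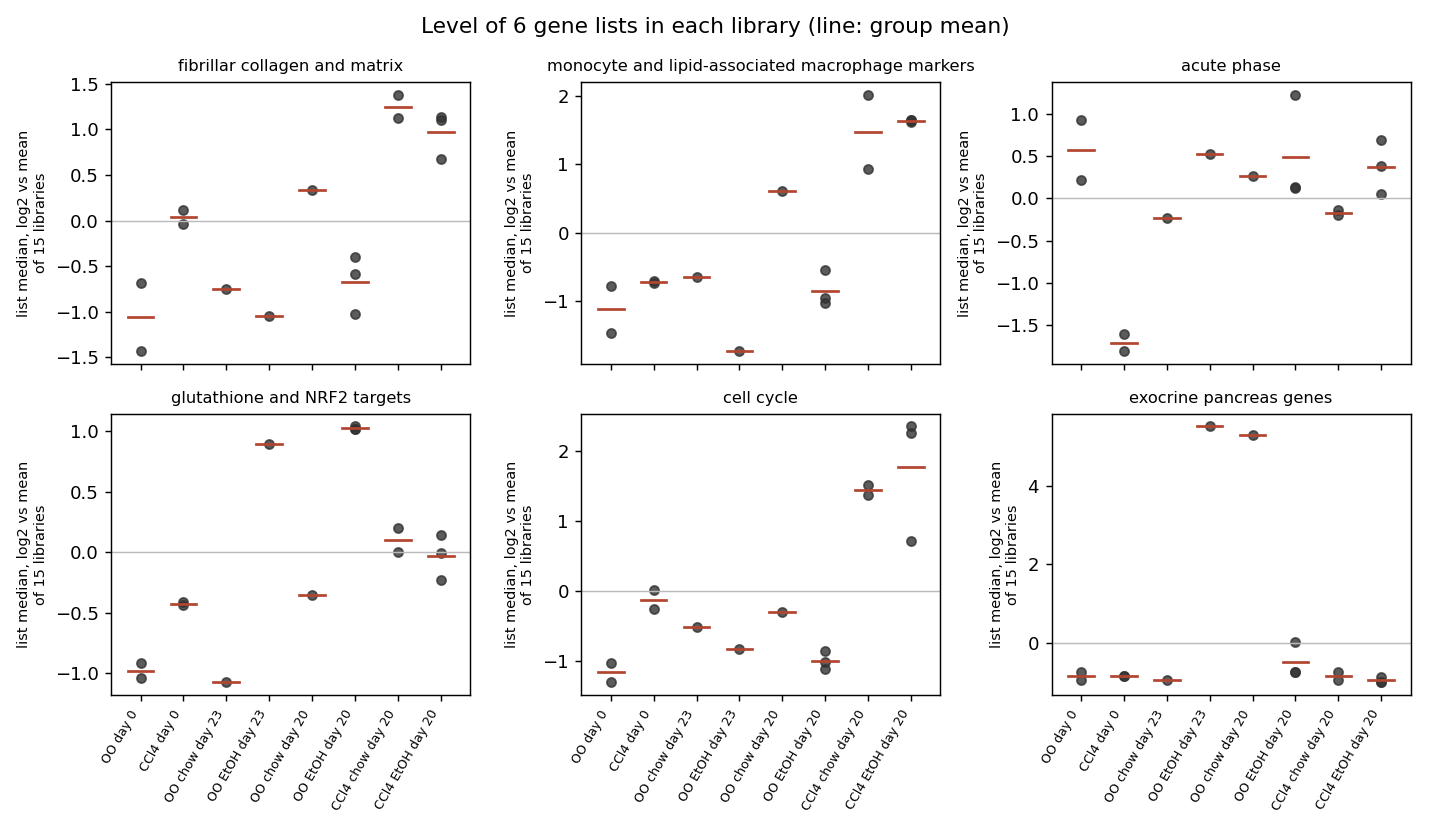
Level of 6 gene lists by group, with 1 point per library and a line at the group mean; the vertical axis is the list's median log2 CPM relative to the mean of the 15 libraries. The exocrine pancreas list stood at 5.31 in library 12 and 5.53 in library 6, against at most 0.016 in the other libraries.

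CCl4 against OO under chow at day 20 asks the same of livers that received no ethanol, with 2 libraries against the single chow library 12. The genes called outside the pancreas include Oat, ornithine aminotransferase of the pericentral hepatocyte, at 47.5 ± 9.15 CPM after CCl4 (SD, n = 2) and 1059 CPM in library 12 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.08e-05). Glul stood at 123 ± 23.5 CPM (SD, n = 2) against 1059 CPM, a log2 change of -3.11 ± 0.35 (SE; edgeR adjusted p = 0.00293); Oat and Glul were picked here after their values were seen. In the day 23 chow library these genes stood at 1305 and 1125 CPM. Of the 3 genes that rose, Aspm, a spindle pole protein of dividing cells, stood at 23.6 ± 3.65 CPM (SD, n = 2) and 2.61 CPM, Abcd2, a peroxisomal fatty acid transporter, rose 4.64-fold, and Cyp39a1, an oxysterol hydroxylase, rose 3.24-fold. They kept their calls with the day 23 chow library, at log2 changes of 3.12, 1.62 and 2.06 (edgeR adjusted p = 0.015, 0.026 and 0.0113). Without library 17 these calls were lost (edgeR adjusted p = 0.124, 0.0904 and 0.207), and those of Aspm (0.0564) and Cyp39a1 (0.0988) also without library 16. On only the 9 day 20 libraries Aspm (0.102) and Abcd2 (0.0699) were not called.

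Exocrine pancreas genes had 8 of 12 lower in this comparison and 12 when adjusted over the list alone (camera, adjusted p = 0.000308 with an estimated correlation); Cel, a lipase gene, stood at 22.4 CPM in library 12 and had 0 counts in both CCl4 chow libraries. With the day 23 chow library as control Cpa1, Prss2 and Cela2a were not called, and the first 2 had a positive log2 change. Outside library 12 and the day 23 ethanol library, Cpa1 and Prss2 reached at most 0.262 and 0.253 CPM without TMM scaling. That sign therefore rests on few reads. In the pericentral list 2 of 16 fell, and 5 fell when adjusted over the list alone (fry, adjusted p = 0.103; camera, adjusted p = 0.16 with an estimated correlation). No gene of the matrix list or the cell cycle list passed over all genes, and 5 of 28 and 15 of 28 were higher when adjusted over the list alone (fry, adjusted p = 0.103 for both; camera, adjusted p = 0.16 with an estimated correlation for both). Of the 28 genes called, 3 were higher and 25 lower, while DESeq2 called 75 higher and 41 lower. Against the day 23 chow library edgeR called 362 genes, 273 higher and 89 lower, and 16 of the 28 were among them. Leaving out library 17 gave 11 genes, and the single chow library is assumed to vary like the other groups.

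CCl4 with ethanol against OO chow at day 20 sets both treatments against neither. Hsd3b5 fell from 132 CPM in library 12 to 0.153 ± 0.0265 CPM (SD, n = 3; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.76e-05). Oat fell 14.4-fold to 73.6 ± 17.4 CPM, Slco1a1 fell 43-fold to 6.17 ± 0.977 CPM and Cyp2e1 fell 8.6-fold to 450 ± 269 CPM (SD, n = 3). Cyp2b10 rose 193-fold to 823 ± 268 CPM, Trem2 rose 6.21-fold to 28.5 ± 4.95 CPM, and the cyclin gene Ccna2 rose 8.2-fold to 26.6 ± 12.9 CPM (SD, n = 3). With the day 23 chow library as control these kept their calls, with Hsd3b5 at 128 CPM in that library and log2 changes of -4.09 for Oat, -6.37 for Slco1a1, -3.18 for Cyp2e1, 7.47 for Cyp2b10, 4.30 for Trem2 and 3.41 for Ccna2. On only the 9 day 20 libraries the calls of Trem2 (edgeR adjusted p = 0.0524) and Ccna2 (0.0555) were lost.

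In the cell cycle list of this comparison 7 of 28 rose, and 23 rose when adjusted over the list alone (fry, adjusted p = 0.0649; camera, adjusted p = 0.287 with an estimated correlation). In the pericentral list 6 of 16 fell, with 7 lower and 1 higher when adjusted over the list alone (fry, adjusted p = 0.0136; camera, adjusted p = 0.22 with an estimated correlation). The bile acid list had 4 of 20 lower, with 8 lower and 1 higher when adjusted over the list alone (fry, adjusted p = 0.0136; camera, adjusted p = 0.22 with an estimated correlation). The P450 list split, with 5 of 27 higher and 4 lower, and 8 and 5 when adjusted over the list alone (fry, adjusted p = 0.103; camera, adjusted p = 0.436 with an estimated correlation). All 12 exocrine pancreas genes were lower than in library 12, over all genes and when adjusted over the list alone (camera, adjusted p = 0.00443 with an estimated correlation). Against the day 23 chow library Cel, Prss2 and Cela2a were not called, and the first 2 had a positive log2 change. Outside library 12 and the day 23 ethanol library, Cel and Prss2 reached at most 0.168 and 0.253 CPM without TMM scaling. That sign therefore rests on few reads. Across all genes edgeR called 414, with 165 higher and 249 lower, and with the day 23 chow library 1001, 630 higher and 371 lower, of which 309 were among the 414. DESeq2 gave 477 higher and 355 lower, and leaving out library 19 gave 345 and 296, so the balance of directions depends on the setting. Leaving out library 18, 19 or 20 gave 222, 641 or 228 genes.

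The interaction asks whether the ethanol effect differed between CCl4 and OO animals. It differed for Cbr3, with a log2 interaction of -5.38 ± 0.58 (SE), and for Abcc4, at -2.98 ± 0.35 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0164 and 0.0235). In OO animals Cbr3 stood at 0.869 CPM with chow and 26.4 ± 8.57 CPM with ethanol (SD, n = 3). In CCl4 animals it stood at 4.13 ± 1.39 CPM with chow (SD, n = 2) and 3 ± 0.0392 CPM with ethanol (SD, n = 3). Abcc4 stood at 9.48 and 107 ± 19.3 CPM in OO animals and at 12.5 ± 2.63 and 17.9 ± 3.47 CPM in CCl4 animals. Cbr3 lies on chromosome 16 at 93683215 to 93690990 on the plus strand of mm10, and Abcc4 on chromosome 14 at 118482692 to 118706219 on the minus strand.

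The glutathione and NRF2 list had a median log2 interaction of -1.61, with 1 of 21 lower over all genes, and 15 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 0.0126 with an estimated correlation). Its median with the day 23 chow library was -2.23 (camera, adjusted p = 0.00443 with an estimated correlation). The Kupffer cell list had a median of 1.20 and the monocyte list 1.45, with no member called over all genes and 11 of 14 and 13 of 16 higher when adjusted over the list alone (camera, adjusted p = 0.0268 and 0.0485 with an estimated correlation). These macrophage lists, with the day 23 chow library, had medians of 0.48 and 0.51 (camera, adjusted p = 0.25 and 0.605 with an estimated correlation). No gene of the P450 list passed over all genes, with 1 of 27 higher and 4 lower when adjusted over the list alone (fry, adjusted p = 0.0911; camera, adjusted p = 0.231 with an estimated correlation). Cbr3 and Abcc4 were the 2 genes called, against 1215 genes at an unadjusted p under 0.05 in edgeR, 152 called by DESeq2 and 35 by limma-voom. Leaving out library 18 gave 0 calls, with an edgeR adjusted p of 0.0594 for both genes, and library 16 left 1, with 0.12 for Abcc4. On only the 9 day 20 libraries the adjusted p was 0.144 for Cbr3 and 0.152 for Abcc4. The other counts were 21, 3, 2, 10, 6 and 5 without libraries 13, 14, 15, 17, 19 and 20.

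**Figure D3:**
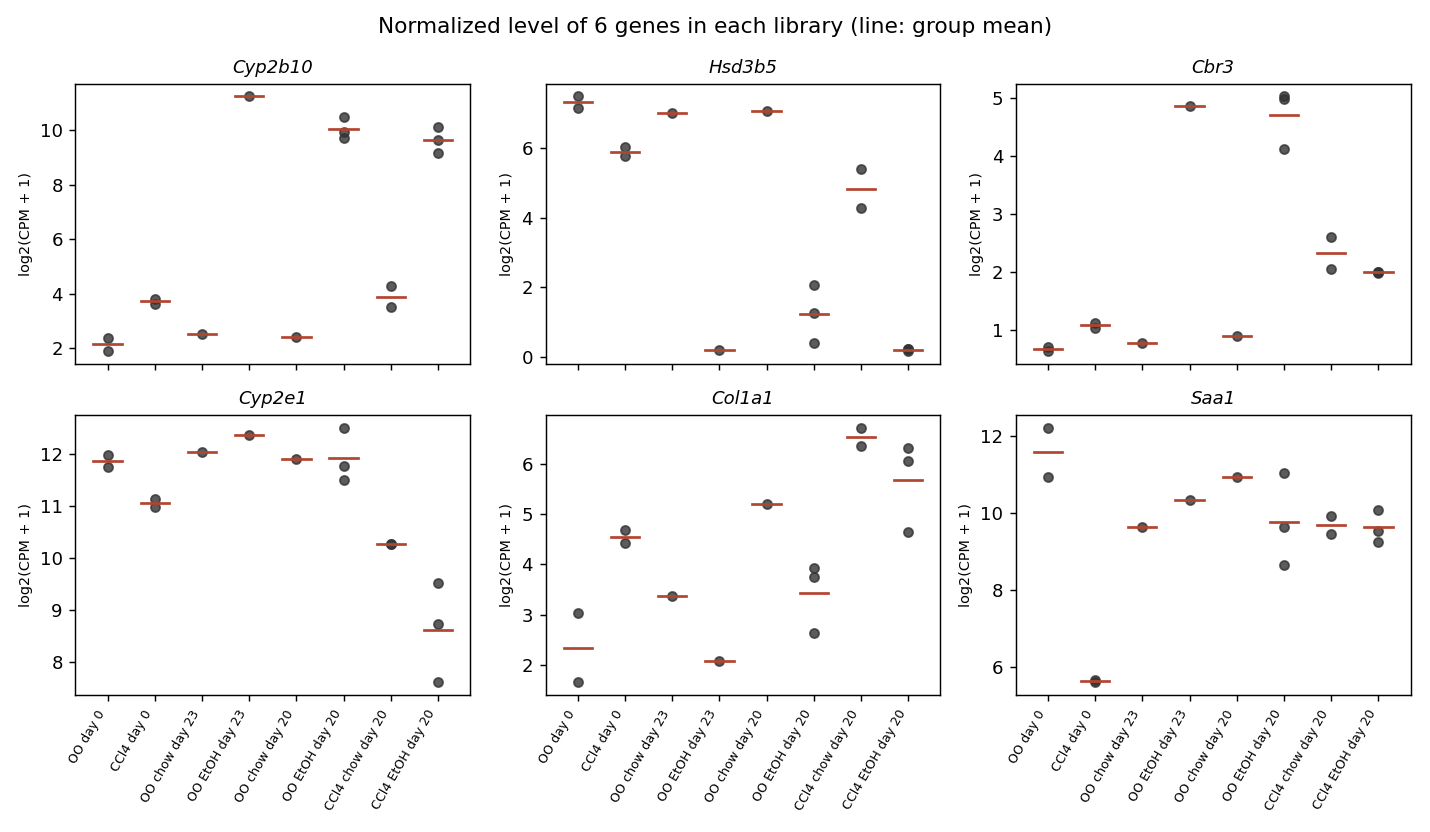
Normalised level of 6 genes by group as log2(CPM + 1), with 1 point per library and a line at the group mean of the plotted values. Cbr3 stood at a mean of 26.4 CPM in OO livers with ethanol at day 20 and at 3 CPM in CCl4 livers with ethanol, and Cyp2b10 at 1093 and 823 CPM.

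CCl4 livers at day 20 with chow against CCl4 livers at day 0 show what changed over the second phase without ethanol, with 2 libraries in each group. Genes called higher included neutrophil and acute-phase genes. Lcn2 rose 65.5-fold from 6.56 ± 2.85 to 438 ± 156 CPM (SD, n = 2; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00142). S100a9, a calcium-binding protein of neutrophils, rose 18.9-fold to 97.6 ± 8.52 CPM, Ltf rose 30.9-fold to 41.3 ± 8.64 CPM and Orm2 rose 30.3-fold to 431 ± 99.2 CPM (SD, n = 2). Csf1r rose 3.26-fold to 241 ± 7.38 CPM. Cyp4a14 fell 49.3-fold from 135 ± 17.4 to 2.76 ± 1.17 CPM, Cyp3a11, a main drug-oxidising P450, fell 6.52-fold to 1582 ± 202 CPM, and Gls2 fell 3.1-fold to 232 ± 23.7 CPM (SD, n = 2). The same CCl4 day 0 libraries enter the day 0 comparison, where Lcn2 and Orm2 fell and Gls2 rose against OO livers. The opposite changes here are therefore not independent of those. The same holds for the acute-phase, Kupffer cell and periportal lists below.

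All 15 neutrophil genes rose, over all genes and when adjusted over the list alone (camera, adjusted p = 0.0405 with an estimated correlation). In the Kupffer cell list 13 of 14 rose, the same number when adjusted over the list alone (camera, adjusted p = 0.0405 with an estimated correlation). The interferon-stimulated list had 18 of 20 higher and 19 when adjusted over the list alone, and the monocyte list 13 of 16 and 15 (fry, adjusted p = 0.00113 and 0.00306; camera, adjusted p = 0.0833 with an estimated correlation for both). In the matrix list 20 of 28 rose, and 26 rose when adjusted over the list alone (fry, adjusted p = 0.00684; camera, adjusted p = 0.109 with an estimated correlation). The acute-phase list had 9 of 22 higher and 14 when adjusted over the list alone (fry, adjusted p = 0.0117; camera, adjusted p = 0.173 with an estimated correlation). In the list of inflammatory cytokines and NF-kB targets 10 of 24 rose, and 15 rose when adjusted over the list alone (fry, adjusted p = 0.00306; camera, adjusted p = 0.0833 with an estimated correlation), with Cxcl16, a chemokine of macrophages, 2.41-fold higher. Urea cycle and amino acid genes went down, 14 of 20 over all genes and 17 when adjusted over the list alone (fry, adjusted p = 0.00306; camera, adjusted p = 0.0833 with an estimated correlation), and so did 6 of 16 periportal genes, with 10 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 0.0405 with an estimated correlation). Across all genes edgeR called 1694, with 1074 higher and 620 lower at day 20. The groups differ in time, in the later CCl4 dose and in the second phase, and leaving out library 3, 4, 16 or 17 gave 281, 262, 796 or 605 genes.

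At day 23 there was 1 OO ethanol library and 1 OO chow library, so the values below compare those libraries and have no replicate check. The P450 list had a median log2 ratio of 1.60, ethanol over chow, with 25 of 27 members higher, and the glutathione and NRF2 list 1.79 with 18 of 21 higher. Both medians stood at percentile 100 among 10000 random lists of equal size matched on mean expression. Of the 31 lists tested, 20 lay in an outer tail of their random lists. Random lists hold unrelated genes, so an extreme percentile does not set a list of related genes apart. Cyp2b10 stood at 2432 CPM against 4.81 CPM, Cbr3 at 28.3 against 0.715 CPM and Abcc4 at 118 against 8.19 CPM. Hsd3b5 stood at 0.151 CPM with ethanol and 128 CPM with chow. The fatty acid synthesis list had a median of -0.72, with 16 of 18 lower, and the interferon-stimulated list -0.80, with 19 of 20 lower. The monocyte list had a median of -0.67, with 12 of 16 lower, the neutrophil list -0.65, with 13 of 15 lower, the Kupffer cell list -0.40, with 13 of 14 lower, and the matrix list -0.34, with 23 of 28 lower. Their percentiles were 0, 0.7, 0 and 0. All 12 exocrine pancreas genes were higher in the ethanol library.

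Fold changes were compared across genes between comparisons that share no library; genes are not independent replicates, so these carry no p. The ethanol effects in OO and CCl4 animals had a Pearson correlation of 0.478 and a Spearman correlation of 0.441 across 14778 genes, with 32 genes called higher in both, against 0.906 for independent lists, and 38 called lower in both, against 2.73. Of the 181 genes higher with ethanol in OO animals at day 20, 174 had a ratio above 1 in the day 23 pair, which includes Cyp2b10. Of the 357 lower genes, 316 had a ratio below 1 there, with a median log2 ratio of -0.669 over the 357. The correlation of these effects was 0.428 (Spearman 0.499), or 0.707 (Spearman 0.569) over the 8265 genes with a mean of at least 10 CPM. The CCl4 effects at day 0 and under chow at day 20 had a correlation of 0.309 (Spearman 0.265), with 2 genes shared higher and 10 shared lower, against 0.0284 and 0.277. The CCl4 effects under ethanol and under chow had a correlation of 0.493 (Spearman 0.527), with 3 genes shared higher and 13 lower, against 0.382 and 2.76, a pair chosen after the data were seen.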

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

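The tests of the interaction with the day 23 chow library were chosen after the results were seen; the tests of the interaction itself were fixed before.

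The ethanol effect differed between CCl4 and OO animals for Cbr3, with a log2 interaction of -5.38, and for Abcc4, with -2.98 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0164 and 0.0235). These genes are listed here because the test of the difference between groups passed. Over the alternatives the adjusted p ran from 6.55e-11 to 0.144 for Cbr3 and from 6.55e-11 to 0.152 for Abcc4, with the highest values on only the 9 day 20 libraries. Without library 18 it was 0.0594 for both, and without library 16 it was 0.12 for Abcc4. It was 0.00978 for both with the day 23 chow library. In OO animals all 3 day 20 ethanol libraries had more Cbr3 and Abcc4 than the chow library.

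Among lists, the glutathione and NRF2 targets had a median log2 interaction of -1.61 and kept its direction with the day 23 chow library, at -2.23 (camera, adjusted p = 0.0126 and 0.00443 with an estimated correlation). The Kupffer cell and macrophage list, with a median of 1.20, and the monocyte and lipid-associated macrophage list, with 1.45, passed with the day 20 chow library (camera, adjusted p = 0.0268 and 0.0485 with an estimated correlation). They stood at 0.48 and 0.51 with the day 23 chow library and did not pass (camera, adjusted p = 0.25 and 0.605 with an estimated correlation). No explanation of these interactions was tested.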

How the results depend on the processing

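The tests with the day 23 OO chow library, and those without libraries 6 and 12, were chosen after the results were seen, as was the agreement of the CCl4 effects under ethanol and chow.

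The counts in the comparisons were 304 for CCl4 at day 0, 538 for ethanol in OO, 187 for ethanol in CCl4, 3509 for CCl4 under ethanol, 28 for CCl4 under chow, 414 for CCl4 with ethanol, 2 for the interaction and 1694 for day 20 against day 0. With no filter the counts changed to 51 for CCl4 under chow and 49 for the interaction. Against a fold of 1.5 with glmTreat the counts changed to 98 for CCl4 at day 0, 117 for ethanol in OO, 56 for ethanol in CCl4, 1117 for CCl4 under ethanol, 176 for CCl4 with ethanol and 412 for day 20 against day 0. With DESeq2 the counts changed to 734 for CCl4 at day 0, 953 for ethanol in OO, 412 for ethanol in CCl4, 116 for CCl4 under chow, 832 for CCl4 with ethanol and 152 for the interaction. With limma-voom the counts changed to 35 for the interaction. With limma-voom and lane as a random block the counts changed to 55 for the interaction. On only the compared libraries the counts changed to 2240 for CCl4 at day 0, 99 for ethanol in CCl4 and 2319 for CCl4 under ethanol. On only the 9 day 20 libraries the counts changed to 201 for ethanol in OO, 18 for CCl4 under chow, 163 for CCl4 with ethanol and 0 for the interaction. With day 20 and 23 OO libraries merged the counts changed to 1139 for ethanol in OO and 20 for the interaction. After merging the day 23 OO chow library the counts changed to 219 for CCl4 under chow and 1576 for CCl4 with ethanol. With those libraries merged and day as a covariate the counts changed to 1461 for ethanol in OO. With the day 23 OO chow library as control the counts changed to 93 for ethanol in OO, 362 for CCl4 under chow, 1001 for CCl4 with ethanol and 10 for the interaction. Leaving out 1 library at a time gave 52 to 121 for CCl4 at day 0, 262 to 796 for day 20 against day 0, 253 to 1554 for ethanol in OO, 2223 to 3981 for CCl4 under ethanol, 0 to 21 for the interaction, 49 to 141 for ethanol in CCl4, 11 to 20 for CCl4 under chow and 222 to 641 for CCl4 with ethanol. Counts not listed for a setting were within 1.5 times. The interaction count of 0 on the 9 day 20 libraries and without library 18 came with 979 and 1037 genes at an unadjusted p under 0.05 in edgeR; DESeq2 (152) and limma-voom (35) were run on all 15 libraries. A tested fold of 1.5 lowers a count by its construction, and for the other settings the cause was not tested. Genes called both in the reported test and under a setting had the same sign in every setting.

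The balance of directions turned under some settings, and the cause was not tested. For CCl4 at day 0, 140 genes were higher and 164 lower, against 388 and 346 with DESeq2. For ethanol in OO, 181 genes were higher and 357 lower, against 514 and 439 with DESeq2, 634 and 505 with day 20 and 23 OO libraries merged, 780 and 681 with those libraries merged and day as a covariate, 849 and 705 without library 13 and 56 and 37 with the day 23 OO chow library as control. For CCl4 under ethanol, 1880 genes were higher and 1629 lower, against 1910 and 2071 without library 13. For CCl4 under chow, 3 genes were higher and 25 lower, against 75 and 41 with DESeq2, 161 and 58 after merging the day 23 OO chow library and 273 and 89 with the day 23 OO chow library as control. For CCl4 with ethanol, 165 genes were higher and 249 lower, against 265 and 257 with no filter, 477 and 355 with DESeq2, 879 and 697 after merging the day 23 OO chow library, 345 and 296 without library 19 and 630 and 371 with the day 23 OO chow library as control. For the interaction, 0 genes were higher and 2 lower, against 29 and 20 with no filter, 84 and 68 with DESeq2, 26 and 9 with limma-voom, 44 and 11 with limma-voom and lane as a random block, 11 and 10 without library 13 and 8 and 2 without library 17.

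Of 147 list tests that passed, 13 passed with an estimated correlation, 146 with RLE scaling and 72 with fry in the same direction, and fry called 73 in total. The correlation of ethanol effects at day 20 and day 23 moved from 0.428 to 0.707 for genes with a mean of at least 10 CPM.

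Named genes changed sign in 110 cases, of which 11 were of genes that had passed and 99 of genes that had not, with 44 of the 99 from leaving out 1 library; the adjusted p of those 99 was 0.133 to 1. All 11 changes of genes that had passed came with the day 23 OO chow library as control, and most were of exocrine pancreas genes. In libraries other than 6 and 12, Cpa1, Cpb1, Pnlip, Cel and Prss2 reached at most 0.262, 0.0517, 0.168, 0.168 and 0.253 CPM without TMM scaling. Their log2 changes against that library therefore rest on few reads. The cause was not tested. With RLE scaling log2 changes became 0.016 for Fasn (CCl4 under ethanol). With no filter log2 changes became 0.011 for Hnf4a (ethanol in CCl4) and 0.014 for Fasn (CCl4 under ethanol). With a filter of 1 CPM in 2 libraries log2 changes became 0.0063 for Fasn (CCl4 under ethanol). With DESeq2 log2 changes became 0.017 for Fasn (CCl4 under ethanol). For CCl4 at day 0, with limma-voom, they became 0.36 for Timp1. For CCl4 under ethanol, with limma-voom, they became -0.12 for Acta2 and 0.19 for Fasn. For the interaction, with limma-voom, they became -0.093 for Acta2. For day 20 against day 0, with limma-voom, they became 0.30 for Acta2. For CCl4 at day 0, with limma-voom and lane as a random block, they became 0.55 for Timp1. For ethanol in OO, with limma-voom and lane as a random block, they became -0.064 for Cyp2e1. For CCl4 under ethanol, with limma-voom and lane as a random block, they became -0.12 for Acta2 and 0.16 for Fasn. For CCl4 under chow, with limma-voom and lane as a random block, they became 0.039 for Acta2. For the interaction, with limma-voom and lane as a random block, they became -0.15 for Acta2 and 0.16 for Timp1. For day 20 against day 0, with limma-voom and lane as a random block, they became 0.26 for Acta2. On only the compared libraries log2 changes became 0.041 for Fasn (CCl4 under ethanol). With day 20 and 23 OO libraries merged log2 changes became -0.059 for Hnf4a (ethanol in OO), -0.042 for Lcn2 (the interaction) and 0.054 for Hnf4a (the interaction). After merging the day 23 OO ethanol library log2 changes became 0.10 for Krt19 (CCl4 under ethanol), 0.20 for Ccl2 (CCl4 under ethanol) and 0.19 for Fasn (CCl4 under ethanol). After merging the day 23 OO chow library log2 changes became 0.30 for Acta2 (CCl4 under chow), 0.58 for Lcn2 (CCl4 under chow) and 0.17 for Alb (CCl4 with ethanol). With those libraries merged and day as a covariate log2 changes became -0.67 for Ccl2 (ethanol in OO) and -0.038 for Hnf4a (ethanol in OO). For ethanol in OO, with the day 23 OO chow library as control, they became 1.97 for Cpb1, 2.82 for Pnlip, 3.34 for Cel, 1.01 for Gpnmb, 0.030 for Csf3r, 0.47 for Ngp, 4.02 for Prss2, 0.21 for Col1a1, 0.31 for Acta2, 1.34 for Timp1, 0.27 for Trem2, 0.50 for Saa1, -0.023 for Cyp2e1 and -0.13 for Hnf4a. For CCl4 under chow, with the day 23 OO chow library as control, they became 2.40 for Cpa1, 2.40 for Prss2, 0.76 for Acta2, 1.70 for Lcn2 and 0.13 for Saa1. For CCl4 with ethanol, with the day 23 OO chow library as control, they became 1.74 for Cel, 1.74 for Prss2, 0.42 for Acta2, 0.085 for Saa1, 1.98 for Cdkn1a and 0.50 for Alb. For the interaction, with the day 23 OO chow library as control, they became -0.92 for Col1a1, -0.45 for Col3a1, -0.65 for Acta2, -1.23 for Lcn2, -0.54 for Saa1, -1.02 for S100a9, -0.61 for Cdkn1a, -0.088 for Alb and 0.13 for Hnf4a. Without libraries 6 and 12 log2 changes became 0.00097 for Hnf4a (ethanol in CCl4) and 0.023 for Fasn (CCl4 under ethanol). For CCl4 at day 0, leaving out 1 library gave -1.36 to 2.16 for Timp1, -0.16 to 1.55 for Cyp7a1 and -0.0038 to 0.40 for Fasn. For day 20 against day 0, leaving out 1 library gave -0.78 to 1.11 for Acta2, -1.92 to 0.17 for Krt19 and -0.17 to 0.20 for Alb. For ethanol in OO, leaving out 1 library gave -0.27 to 0.28 for Cyp2e1, -0.066 to 0.16 for Hnf4a and -1.73 to 0.038 for Timp1. For CCl4 under ethanol, leaving out 1 library gave -0.33 to 0.13 for Krt19, -0.83 to 0.44 for Saa1, -0.47 to 0.062 for Ccl2, -0.41 to 0.69 for Fasn and -0.42 to 0.39 for Acta2. For the interaction, leaving out 1 library gave -0.62 to 1.10 for Cyp7a1, -0.17 to 0.062 for Hnf4a, -1.62 to 1.27 for Timp1 and -0.39 to 0.42 for Acta2. For ethanol in CCl4, leaving out 1 library gave -0.42 to 0.013 for Ccl2, -0.36 to 0.43 for Fasn, -0.26 to 0.086 for Alb, -0.094 to 0.082 for Hnf4a, -1.99 to 0.92 for Timp1, -0.76 to 0.77 for Krt19, -0.31 to 0.24 for Saa1 and -0.075 to 0.64 for Mki67. For CCl4 under chow, leaving out 1 library gave -0.64 to 0.74 for Cdkn1a, -0.15 to 0.25 for Alb, -0.30 to 1.59 for Spp1 and -0.45 to 0.31 for Lcn2. For CCl4 with ethanol, leaving out 1 library gave -0.13 to 0.054 for Alb and -1.02 to 0.18 for Cyp7a1.

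The filter on low counts set which genes were tested: for the interaction 14778 genes were tested, 19833 with no filter and 13876 with at least 1 CPM in 2 libraries. In 11 pairs of gene and setting both groups had 0 counts and gave no value.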

Other observations

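The tests with the day 23 OO chow library, of pancreatic tissue, of a response to ethanol feeding and of a shift of sex-biased genes were chosen after the results were seen.

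CCl4 against OO gave 28 calls under chow, 20 without library 16 and 11 without library 17, and 3509 under ethanol, 2223 without library 18. In the ethanol comparison reduced to 2 CCl4 libraries and 1 OO library, the median was 1591 calls over 9 subsets, with a range of 884 to 3050. Each subset also took the left-out libraries out of the shared estimate of spread, while the chow test kept them. The subsets therefore do not isolate the number of libraries, and its part in the gap stays open. Against the day 23 OO chow library the count under chow was 362, so a day 20 OO chow library that stands apart is a candidate explanation for part of the gap. Day, substudy, second-phase OO and library cannot be separated there, since each day has 1 OO chow library. The labels place the days in different substudies and name OO again only for the second phase of the day 20 OO arms. A CCl4 effect that depends on feeding stays open, and the interaction test called 2 genes with edgeR, 152 with DESeq2 and 35 with limma-voom.

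Exocrine pancreas transcripts summed to 178 CPM in the day 20 OO chow library and 162 CPM in the day 23 OO ethanol library. A response to ethanol feeding is argued against, since the highest day 20 ethanol library had 12.7 CPM and the first of the 2 libraries had no ethanol. Of 12 genes tested, 11 were above 10 times the median of the other 13 libraries in both, the exception being Cela1, and the gene levels of the 2 libraries had a Spearman correlation of 0.818. Pancreatic tissue carried along when the liver was excised may be the source.

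Of 20 male-biased liver genes, 5 fell with ethanol in OO males and 15 in CCl4 males, with median log2 changes of -1.33 and -2.70 (fry, adjusted p = 0.019 and 6.53e-05; camera, adjusted p = 0.119 and 0.00098 with an estimated correlation; interaction, fry adjusted p = 0.0427 and camera adjusted p = 0.0517 with an estimated correlation). A female animal among the ethanol libraries is argued against by Y-linked genes, whose lowest sum in an ethanol library was 0.642 of the median of libraries without ethanol. Of the 4 list tests that a shift toward the female pattern may be expected to pass, 3 passed with fry. Female-biased genes outside the P450 family had a fry adjusted p of 0.269 in OO animals and 0.0488 in CCl4 animals (camera, adjusted p = 0.382 and 0.0812 with an estimated correlation), which keeps the shift open. The lists were composed after the largest ethanol effects were seen. Male-biased genes also fell with CCl4 under ethanol, 16 of 20 at a median of -2.19 (fry, adjusted p = 0.000267, and camera, adjusted p = 0.0426 with an estimated correlation). That comparison uses the same CCl4 ethanol libraries. For CCl4 without ethanol the list did not pass, at a median of -0.36 at day 0 (fry, adjusted p = 0.0545, and camera, adjusted p = 0.225 with an estimated correlation) and -0.51 under chow at day 20. Without ethanol, 14 of 20 had a negative log2 change at day 0, with 3 called lower, and 17 of 20 had a negative change under chow. The direction was thus the same, but the list passed only among ethanol-fed animals. Whether CCl4 lowers these genes without ethanol stays open.

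For CCl4 against OO under ethanol, the 6 libraries allow 10 splits into groups of 3, of which 1, the real split, gave as many calls, and 10 are too few for a share under 0.05. The real split gave 3509 calls and the highest other split 0 (edgeR). Every other split mixes CCl4 and OO libraries in both groups, so a treatment difference widens the spread within its groups and lowers its calls.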
